A study of Homo sapiens with 8 samples.

How the data were processed

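RNA of single MCF-7 cells was measured in 8 libraries, 2 at each of 0, 2, 8 and 24 h of 1 nM estradiol after 2 days without hormone. Per the labels' protocols, cells were isolated in droplets on a ddSEQ instrument and libraries were made with the SureCell WTA 3′ kit. STAR 2.5.2b and featureCounts 1.5.3 are named, per the submitters' processing notes, together with the human builds hg19 and hg38 without a role for either, so no coordinates are given. The authors deposited 1 table of raw counts per gene and cell for all libraries, and a second table naming the library of each cell. Whether reads were collapsed to unique molecules, and whether the counting used strand, is not given in the sources used here. The fixed tests had assumed unique molecules, and the word counts is used for that reason throughout.

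The deposited counts covered 2227 cells and 16359 genes, 23 of them at 0 in every cell, and summed to 13530178. Counts per cell ran from 1503 to 20507, genes per cell from 910 to 4494, and the mitochondrial share reached at most 19.9%, so cells had been filtered before deposit. No further cell was left out in the main results. No doublet caller was run, and leaving out the 5% of cells with the most counts in each library served as an alternative. The letters a and b in the cell names were read as replicates 1 and 2 of the labels, which the files do not state. The 2 libraries of a time were compared with random splits of their pooled cells: chi-square over degrees of freedom was 1.51, 1.27, 1.72 and 1.52 at 0, 2, 8 and 24 h, against medians of 1.16 to 1.26 for 100 random splits, of which 0, 9, 0 and 4 were as large. They thus differed by more than every split at 0 and 8 h and lay within the range of the splits at 2 and 24 h, and were kept as separate libraries, as the labels have them.

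Counts were summed over the cells of each library, since cells are not replicates. All 8 sums were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter, a robust quasi-likelihood fit and time as a factor of 4 levels, which left 4 residual degrees of freedom. The filter kept 10808 genes with 99.2% of the counts, and the common biological coefficient of variation was 0.0596. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are given with 95% intervals and SEs, the SE being the size of the log2 fold change over the square root of F. The intervals use a normal distribution despite the few residual degrees of freedom, so they may be too narrow. They are not adjusted for the number of genes, so an interval can exclude no change without a call. For genes named by fold change, that choice also favours large values. Levels are in CPM.

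The genes named were set by a fixed rule. It took up to 12 rises and 8 falls in each comparison with 0 h, and up to 5 of each between successive times, by fold change among called genes with a mean of at least 20 counts per library and no overlap between the libraries compared. It added 16 known target or receptor genes and 2 to 4 members of each list by smallest adjusted p. The mitochondrial rRNA genes fall outside the rule and were chosen after their values were seen. Of 18 gene lists fixed beforehand, 16 had at least 5 tested members and were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and with an estimated one, and with fry. The 48 list tests formed 1 family, in which camera called 32 with the preset and 12 with the estimated correlation, and fry called 29. The lists had 72, 13, 44, 56, 26, 20, 20, 12, 20, 21, 20, 18, 16, 29, 19, 16, 13 and 78 symbols, for early estrogen response, lowered by estrogen, S phase, G2M phase, ribosome biogenesis, immediate early, unfolded protein response, heat shock, cholesterol synthesis, glycolysis and hypoxia, interferon response, p53 targets, luminal, oxidative phosphorylation, basal and mesenchymal, immune and endothelial, mitochondrially encoded and ribosomal protein genes. Lists of known estrogen targets rest largely on earlier work in this same cell line. The basal and mesenchymal list had 4 tested members and the immune and endothelial list 1, so these were read as levels only.

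Per-cell measures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Shares of lists are means over cells of the percent of a cell's counts. For the Fano factor, the correlation between list parts and the percent of cells with a count, each cell was thinned to 3000 counts, the largest multiple of 100 that at least 70% of cells reached in every library. Library values were compared by an exact permutation test of the F ratio over 2520 assignments to 4 times, whose smallest p is 0.00952. A comparison of 2 libraries with 2 cannot reach 0.05, so times were tested together. Beside them stand 1000 random lists matched on mean expression over the cells of all libraries. The fixed wording left open whether the 16 followed genes form a family of their own or join the 5 measures in a family of 21 tests. The family of 16 was taken as the main reading.

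Counts were simulated for 10808 genes, with 100 genes changed 1.5-fold and 100 changed 2-fold at 1 time. The edgeR script recovered 35%, 38% and 38% of genes changed 1.5-fold and 74%, 71% and 72% of those changed 2-fold at 2, 8 and 24 h, with 6.84%, 6.03% and 4.35% of its calls false. In a simulated 8 h comparison of 10808 genes with 30 early estrogen genes raised 1.5-fold, camera called that list and 0 of 47 other tests. Genes were drawn independently there, so it says nothing on false calls among correlated genes. In 8 crossed comparisons, 1 library of each of the 4 times was set against the other, with time as a term. Each used all 8 libraries, unlike a comparison of 2 times. They gave a median of 0 and at most 2 calls in edgeR, where 3.24% to 6.49% of genes had an unadjusted p under 0.05. DESeq2 1.42.0 gave a median of 0 and at most 1 call, and 0.157% to 0.703% of genes had such a p. Alternatives were DESeq2, its size factors in edgeR, scaling by total counts only, voom, no filter on low counts, thinned libraries, a block for the replicate number, the libraries of 2 times alone, other sets of cells, other list parts and thinning depths, and each library left out in turn, where the lone library of a time was assumed to vary like the others. Cells with 1 to 5% mitochondrial counts, the extra-Poisson variation and the family of 21 tests were added after the data were seen. Over all scalings the median log2 fold change of all genes lay between −0.0535 and 0.0116.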

Results

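Transcript counts were measured in single MCF-7 cells, an established human breast cancer line that carries the estrogen receptor and divides in response to estrogen. The cells were kept without hormone for 2 days and then either left untreated (0 h) or exposed to 1 nM estradiol, the main natural estrogen, for 2, 8 or 24 h. Each of the 4 times had 2 libraries, which gave 8 libraries and 2227 cells in all, with 207 to 360 cells per library. Total counts ranged from 1340386 to 2163710 per library. The median count per cell lay between 4452 and 5617.5 in the 6 libraries of 0, 2 and 8 h, and was 8378 and 7916.5 in the libraries of 24 h. The question of the series is what sets the extent of the estrogen response in single cells. The labels do not say whether the libraries of a time came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The gene lists, the named-gene rule, the tests and most alternatives were chosen before the data were examined.

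The share of cells with 10% or more of their counts in mitochondrial genes moved with time. It was 12.2 ± 0.445% at 0 h, 10.1 ± 3.46% at 2 h, 34.9 ± 0.753% at 8 h and 38.9 ± 2.39% at 24 h (SD, n = 2 libraries). Markers of other cells were scarce in every library. The 7 basal and mesenchymal genes in the table took 0.00694% to 0.0137% of a library's counts, and the 1 blood or endothelial gene in the table, the hemoglobin gene HBA1, took at most 0.000836%. Luminal genes, which mark the epithelial type that MCF-7 belongs to, took 1.27% to 1.87%.

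After 2 h of estradiol LIF, a cytokine of the interleukin-6 family, was 12.97-fold higher than in untreated cells (95% interval 7.44 to 22.6), with 28.7 ± 2.24 against 2.11 ± 0.304 CPM (SD, n = 2). PHLDA1 rose 10.9-fold (8.74 to 13.7), EGR3, a zinc-finger transcription factor of the early growth response family, 9.38-fold (6.99 to 12.6) and MYBL1, a relative of the MYB transcription factor, 7.44-fold (5.13 to 10.8). AREG, which encodes the epidermal growth factor receptor ligand amphiregulin, went from 62.17 ± 12.996 to 382 ± 15.5 CPM (SD, n = 2), and SLC7A5, which encodes an amino acid transporter, from 19.2 ± 0.406 to 120 ± 0.368. Also higher at 2 h were LONRF2 (6.17-fold), the nuclear receptor gene NR4A1 (6.05-fold), OSGIN1 (5.95-fold), FOXC1 (5.65-fold), the pro-apoptotic gene PMAIP1 (5.42-fold) and FHL2 (5.06-fold).

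CCNG2, which encodes a cyclin linked to growth arrest, fell at 2 h by 2.08 ± 0.19 on the log2 scale (SE), from 97.7 ± 11.9 to 22.9 ± 1.07 CPM (SD, n = 2). The lactate receptor gene HCAR1 was 3.61-fold lower, DMRTA1 3.42-fold, the homeobox gene HOXC13 3.23-fold, NECTIN4 3.16-fold, the Wnt receptor gene FZD2 3.12-fold, ARID4A 3.05-fold and the ephrin receptor gene EPHA4 3.02-fold. In all, 924 of 10808 genes tested changed at 2 h, 568 of them higher and 356 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Changes of over 2-fold were seen in 230 of the higher and 104 of the lower genes. The count was 270 with DESeq2 and 325 in cells with 1 to 5% mitochondrial counts, and it dropped to 545 and 599 without replicate 1 or 2 of 0 h and to 451 and 472 without replicate 1 or 2 of 2 h. NECTIN4 lost its call without replicate 2 of 2 h (adjusted p = 0.0913, edgeR) and with DESeq2 (adjusted p = 0.102), and in cells with 1 to 5% mitochondrial counts the calls of NECTIN4 (edgeR adjusted p = 0.114), DMRTA1 (0.639) and EPHA4 (0.158) ended.

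Of the 16 known estrogen target or receptor genes followed throughout, 12 were higher at 2 h. XBP1, a transcription factor of the secretory pathway, rose 2.20-fold (1.93 to 2.501), the growth regulator MYC 2.06-fold (1.77 to 2.39), the estrogen-induced gene GREB1 1.84-fold (1.53 to 2.22), the ubiquitin ligase gene SIAH2 1.82-fold (1.52 to 2.19), the cyclin D1 gene CCND1 1.80-fold (1.59 to 2.04) and the secreted trefoil factor gene TFF1 1.504-fold (1.32 to 1.71). The chemokine gene CXCL12 rose 3.93-fold, the retinoic acid receptor gene RARA 1.47-fold, IGFBP4 1.36-fold and the cathepsin D gene CTSD 1.27-fold, beside AREG and EGR3. ESR1, which encodes the estrogen receptor itself, fell by 0.46 ± 0.14 on the log2 scale (SE, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0255). NRIP1 was at 1.08-fold (0.852 to 1.37) and the progesterone receptor gene PGR at 3.89-fold (1.45 to 10.4), and neither passed the test. PDZK1 had 0 counts in all 6 libraries of 0, 2 and 8 h and 3 and 9 counts in those of 24 h, too few to be tested. Leaving out 1 library ended the calls of ESR1 (edgeR adjusted p = 0.275 without replicate 1 of 0 h, 0.122 and 0.209 without replicate 1 or 2 of 2 h), CTSD (0.148 without replicate 2 of 0 h, 0.162 and 0.0676 without replicate 1 or 2 of 2 h) and IGFBP4 (0.0593 without replicate 2 of 2 h), and gave PGR a call (0.0475 without replicate 2 of 0 h). ESR1 also lost its call without the 10% of cells with the highest mitochondrial share (edgeR adjusted p = 0.0787). DESeq2 made no call for ESR1 (adjusted p = 0.354) or RARA (adjusted p = 0.0619), and in cells with 1 to 5% mitochondrial counts ESR1 (edgeR adjusted p = 0.491), CTSD (0.589) and RARA (0.355) had none.

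**Figure D1:**
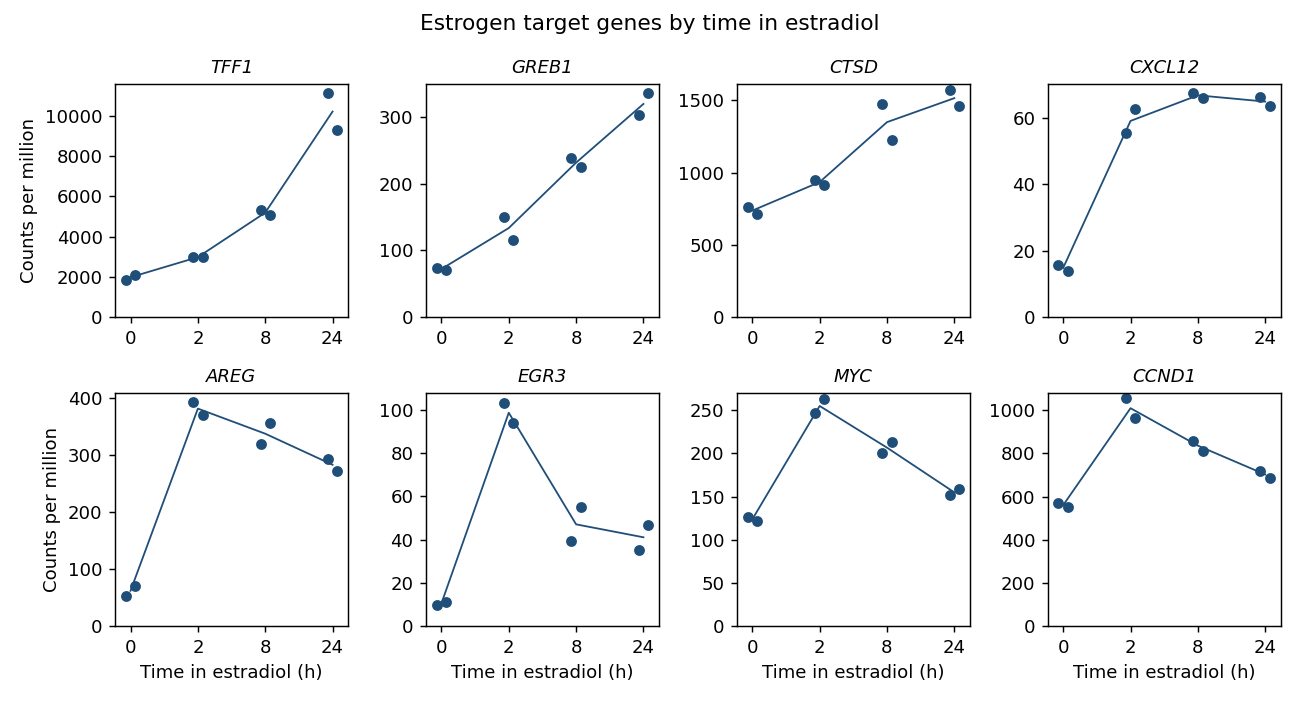
CPM of 8 estrogen target genes (vertical axes, each starting at 0) against time in estradiol in h (horizontal axes, times evenly spaced), with 1 point per library and a line through the mean of the 2 libraries of each time. TFF1 and GREB1 were highest at 24 h, whereas the means of AREG, EGR3, MYC and CCND1 were highest at 2 h.

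The gene lists moved as follows at 2 h. Of 65 tested members of the early estrogen list, 32 rose and 0 fell, and 44 rose and 1 fell when adjusted over the list alone. They included AREG, SLC7A5, EGR3 and HSPB8, a small heat shock protein gene (2.59-fold). The list stood above other genes in limma's camera test with a preset correlation (adjusted p = 2.93e-36). Of 12 tested genes known to be lowered by estrogen, 8 fell and 0 rose over all genes and adjusted over the list alone (camera adjusted p = 1.11e-10), among them CCNG2 (4.23-fold), PNRC1 (2.46-fold), the stress gene TP53INP1 (2.65-fold) and the ephrin gene EFNA1 (2.38-fold). Immediate early genes, which respond to growth signals without new protein synthesis, rose in 14 of 18 cases and fell in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 4.83e-28), among them IER3 (3.74-fold), EGR3, NR4A1 and EGR1 (3.25-fold). Of 25 genes of ribosome biogenesis, 12 rose and 0 fell (16 and 2 adjusted over the list alone, camera adjusted p = 4.17e-10), with NOP16 1.90-fold, RRS1 2.16-fold and NIP7 2.06-fold higher. These 4 lists kept their calls with an estimated correlation (adjusted p = 0.00317 to 0.0252).

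Other lists passed camera only with the preset correlation at 2 h. Fry called the unfolded protein response (fry adjusted p = 0.0309) but not ribosomal protein (0.161), oxidative phosphorylation (0.142) or mitochondrially encoded genes (0.288). Of 19 genes of the unfolded protein response, 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0275, adjusted p = 0.317 with an estimated correlation). The 3 were XBP1, ATF4 (1.43-fold) and the chaperone gene HSPA5 (1.32-fold). Of 77 ribosomal protein genes, 5 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 3.01e-10, adjusted p = 0.338 with an estimated correlation), with RPL10 at 0.696-fold and RPL6 at 0.742-fold. Of 26 nuclear genes of oxidative phosphorylation, 4 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.00466, adjusted p = 0.401 with an estimated correlation). UQCRB, a subunit of respiratory complex III, was at 0.681-fold, and CYCS, which encodes cytochrome c, rose 1.46-fold. Of 13 mitochondrially encoded genes, 2 fell, MT-CO1 (0.762-fold) and MT-CYB (0.823-fold), and 3 adjusted over the list alone (camera adjusted p = 0.000487, adjusted p = 0.329 with an estimated correlation). Leaving out 1 library ended the list calls of the unfolded protein response (camera adjusted p = 0.110 without replicate 2 of 0 h, 0.224 without replicate 2 of 2 h), oxidative phosphorylation (0.111 without replicate 1 of 0 h) and the mitochondrial genes (0.647 without replicate 2 of 2 h).

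No list call was made at 2 h for the remaining 8 lists. In the p53 target list of 17 genes, the members went both ways: AEN (2.58-fold) and the cell cycle inhibitor gene CDKN1A (1.67-fold) rose while 4 members fell, among them the pro-apoptotic gene BBC3 (2.47-fold lower). Among 16 luminal genes, 3 rose, with CLDN4 at 1.41-fold and ELF3 at 1.63-fold, and 3 fell, with GRHL2 1.92-fold lower. Of 18 genes of glycolysis and hypoxia, 3 rose and 2 fell, with the glucose transporter gene SLC2A1 at 1.80-fold. Among heat shock genes, 3 of 12 rose, and among cholesterol synthesis genes 2 of 17, with 0 falling in both. Of 10 interferon response genes, ISG20 rose 2.24-fold and IFITM3 fell to 0.738-fold. Of 43 S phase genes, the licensing inhibitor gene GMNN fell to 0.504-fold and RRM2, a subunit of ribonucleotide reductase, rose 1.44-fold, while 1 of 54 G2M genes, CDK1, fell (0.685-fold). Adjusted over the list alone, the counts of higher and lower members were 3 and 6 for p53 targets, 5 and 6 for luminal genes, 3 and 3 for glycolysis and hypoxia, 3 and 1 for heat shock, 2 and 0 for cholesterol synthesis, 1 and 1 for the interferon response, 1 and 1 for S phase and 0 and 0 for G2M. Their camera adjusted p-values lay between 0.166 and 0.982. The G2M list passed as lower without replicate 1 of 0 h (camera adjusted p = 0.0181) and in cells with 1 to 5% mitochondrial counts (0.000333), where the heat shock list passed as higher (0.0138). On the log2 scale the median and mean were 0.02 and −0.04 for the S phase list, whose test pointed down, and 0.05 and −0.30 for glycolysis and hypoxia, whose test pointed up.

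After 8 h of estradiol SLC7A5 stood 6.80-fold (5.404 to 8.56) and AREG 5.53-fold (4.66 to 6.55) above untreated cells. CYP1B1, a cytochrome P450 that oxidizes estradiol, rose 4.62-fold (3.70 to 5.77), from 75.8 ± 12.5 to 354 ± 12.8 CPM (SD, n = 2). MYBL1 was 5.59-fold higher, EGR3 4.53-fold, CXCL12 4.43-fold, OSGIN1 4.15-fold, the vesicle transport gene RAB31 4.13-fold, the zinc transporter gene SLC39A14 3.50-fold and the prostaglandin E synthase gene PTGES 3.50-fold. The mitochondrial genes MT-ATP8 (6.21-fold) and MT-ND6 (5.15-fold) were also higher. MT-ATP8 overlaps MT-ATP6, MT-ND4L overlaps MT-ND4, nuclear copies of mitochondrial genes exist, and MT-ND6 lies on the strand opposite its neighbours, and how the authors' counting treated overlap and strand is not given in the sources used here, so the size of these rises is uncertain.

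Lower at 8 h were AC011487.2, a gene known by a clone-based name (6.24-fold lower), the prostate stem cell antigen gene PSCA (6.07-fold), the mucin gene MUC3A (5.23-fold), the acetylcholinesterase gene ACHE (4.79-fold), the erythropoietin receptor gene EPOR (4.31-fold), ABTB1 (4.26-fold), EPHA7 (3.998-fold) and the chromatin reader gene ING4 (3.78-fold). MUC3A has near-identical relatives, so its counts may be shared with them. PSCA went from 79.9 ± 19.2 to 13.3 ± 0.235 CPM (SD, n = 2). Of 10808 genes tested, 2097 changed, 1090 higher and 1007 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 232 of the higher and 206 of the lower genes changed over 2-fold. The count was 735 with DESeq2, 578 in cells with 1 to 5% mitochondrial counts, 1211 without replicate 1 of 0 h and 1376 without replicate 2 of 0 h.

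Among the followed target genes, PGR passed the test at 8 h, with 8.46 ± 1.42 against 1.495 ± 1.458 CPM (SD, n = 2, 5.97-fold, 2.51 to 14.2). GREB1 was 3.20-fold (2.70 to 3.79) and TFF1 2.62-fold (2.30 to 2.98) above untreated cells. XBP1 was at 1.98-fold, CTSD at 1.83-fold, MYC at 1.67-fold, SIAH2 at 1.497-fold, CCND1 at 1.49-fold, NRIP1 at 1.47-fold and IGFBP4 at 1.33-fold, and all passed. RARA (0.888-fold, 0.744 to 1.06) and ESR1 (0.856-fold, 0.715 to 1.02) did not. NRIP1 lost its call without replicate 2 of 0 h (edgeR adjusted p = 0.0918), without replicate 2 of 8 h (0.143) and with DESeq2 (0.111), and PGR lost its call without replicate 1 of 0 h (0.114). In cells with 1 to 5% mitochondrial counts NRIP1 turned to −0.20 on the log2 scale (edgeR adjusted p = 0.767) and CCND1 (0.0707), EGR3 (0.0718), MYBL1 (0.0511) and SIAH2 (0.368) had no call. ESR1 was called lower in those cells (edgeR adjusted p = 0.00565) and without replicate 2 of 8 h (0.0448).

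In the early estrogen list 45 of 65 members rose and 1 fell at 8 h (46 and 2 adjusted over the list alone, camera adjusted p = 4.83e-28), among them AREG, SLC7A5, RAB31 and TFF1. Of the 12 genes lowered by estrogen, 7 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 1.53e-08), among them TP53INP1 (2.60-fold), the pro-apoptotic genes BIK (2.51-fold) and BMF (2.94-fold), and CCNG2 (2.14-fold). Ribosome biogenesis genes rose in 14 of 25 cases with 0 falling (18 and 0 adjusted over the list alone, camera adjusted p = 2.79e-09), with the dyskerin gene DKC1 at 2.05-fold, NOLC1 at 1.84-fold and POLR1B at 2.43-fold. These 3 lists kept their calls with an estimated correlation (adjusted p = 0.00317 to 0.0335).

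Genes of DNA replication and of protein folding also moved at 8 h. Of 43 S phase genes, 15 rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 4.66e-08, adjusted p = 0.0613 with an estimated correlation), with the flap endonuclease gene FEN1 at 1.95-fold, the replicative helicase gene MCM6 at 1.84-fold, GINS2 at 1.67-fold and CDC6 at 2.56-fold. Of 54 G2M genes, 9 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.00268, adjusted p = 0.294 with an estimated correlation), with RANGAP1 at 1.498-fold and CDCA8 at 1.90-fold. Of 19 genes of the unfolded protein response, 12 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 1.12e-09, adjusted p = 0.0534 with an estimated correlation), among them XBP1, the calreticulin gene CALR (1.53-fold) and PDIA6 (1.45-fold). Of 12 heat shock genes, 5 rose and 1 fell over all genes and adjusted over the list alone (camera adjusted p = 0.000169, adjusted p = 0.0510 with an estimated correlation), with the mitochondrial chaperonin gene HSPD1 at 1.86-fold and HSP90AA1 at 1.55-fold. Of 17 cholesterol synthesis genes, 9 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00139, adjusted p = 0.206 with an estimated correlation), with DHCR7 at 1.70-fold and the squalene epoxidase gene SQLE at 1.68-fold. The G2M list lost its call without replicate 1 of 0 h (camera adjusted p = 0.188) and in cells with 1 to 5% mitochondrial counts (camera adjusted p = 0.276). Fry did not call that list (fry adjusted p = 0.0790).

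Mitochondrially encoded and nuclear genes of the respiratory chain went opposite ways at 8 h. Of 13 mitochondrially encoded genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 1.05e-21, adjusted p = 0.0561 with an estimated correlation), with MT-ND4 at 1.92-fold and MT-ND2 at 1.92-fold, while the share of cells with 10% or more mitochondrial counts was 34.9% against 12.2%. Of 26 nuclear oxidative phosphorylation genes, 13 fell and 1 rose (15 and 1 adjusted over the list alone, camera adjusted p = 2.24e-06, adjusted p = 0.210 with an estimated correlation). UQCRB was at 0.626-fold and COX6A1 at 0.651-fold, and CYCS rose 1.80-fold. Of 77 ribosomal protein genes, 12 fell and 2 rose (8 and 2 adjusted over the list alone, camera adjusted p = 7.93e-07, adjusted p = 0.444 with an estimated correlation), with RPL10 at 0.681-fold and RPL7L1 at 1.54-fold. Ribosomal protein genes have many near-identical copies in the genome, so single members are uncertain. In cells with 1 to 5% mitochondrial counts, a range that limits the mitochondrial share itself, the mitochondrial list was lower at 8 h (camera adjusted p = 1.63e-22), the ribosomal list turned higher without a call (camera adjusted p = 0.186) and the nuclear respiratory list had no call (camera adjusted p = 0.553). Of 16 luminal genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.00458, adjusted p = 0.188 with an estimated correlation), with the keratin genes KRT18 at 0.639-fold and KRT19 at 0.699-fold and the E-cadherin gene CDH1 at 1.44-fold. The mesenchymal gene FN1, which encodes fibronectin, rose 2.60-fold, and SNAI2 was 2.01-fold lower.

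The remaining 4 lists had no camera call at 8 h. Fry did call the immediate early list (fry adjusted p = 0.00906) and that of glycolysis and hypoxia (0.00717). Immediate early genes rose in 6 of 18 cases and fell in 3 (8 and 3 adjusted over the list alone, camera adjusted p = 0.0549), with EGR3, KLF4 (1.94-fold), MYC and NR4A1 (2.33-fold) higher. Of 10 interferon response genes, 5 fell, among them IFITM3 (0.656-fold) and IFI6 (3.48-fold lower), and ISG20 rose 2.06-fold (5 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.0824). Of 18 genes of glycolysis and hypoxia, 4 rose, with the lactate dehydrogenase gene LDHA at 1.99-fold and PFKP at 1.59-fold, and 4 fell, with GAPDH at 0.795-fold, also when adjusted over the list alone (camera adjusted p = 0.145). The median of that list was 0.13 and the mean −0.04 on the log2 scale, and its test pointed up. Of 17 p53 targets, 2 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.309), with AEN at 1.75-fold and BBC3 1.85-fold lower. Leaving out 1 library gave calls to the immediate early list (camera adjusted p = 0.0413 without replicate 2 of 0 h, 0.0102 without replicate 1 of 8 h) and to the interferon list (0.0325 without replicate 2 of 0 h, 0.0145 without replicate 2 of 8 h). In cells with 1 to 5% mitochondrial counts the immediate early list (camera adjusted p = 0.00299) and the list of glycolysis and hypoxia (camera adjusted p = 0.000235) had calls.

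At 24 h CKAP2L, which encodes a mitotic spindle protein, was 7.44-fold (3.89 to 14.2) above untreated cells, the mitotic phosphatase gene CDC25C 5.98-fold (3.39 to 10.54), the helicase gene PIF1 5.72-fold (3.47 to 9.44) and the kinesin gene KIF14 5.27-fold (3.76 to 7.39). TFF1 reached 10199 ± 1304 CPM against 1981 ± 169 (SD, n = 2, 5.15-fold, 4.51 to 5.88), and GREB1 319 ± 24.2 against 72.1 ± 1.91 (4.43-fold, 3.76 to 5.21). MYBL1 was 5.44-fold higher, ARHGAP36 5.34-fold, MT-ATP8 4.95-fold, the histone gene HIST1H4C 4.69-fold, AREG 4.62-fold and TNFAIP8L1 4.52-fold. HIST1H4C belongs to a family of near-identical genes, and its call ended without replicate 1 of 0 h (edgeR adjusted p = 0.209) or replicate 2 of 0 h (0.123). Among cells with 1 to 5% mitochondrial counts HIST1H4C (edgeR adjusted p = 0.632) and KIF14 (0.425) had no call.

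MUC3A was 7.36-fold lower at 24 h, ACHE 7.07-fold, PSCA 6.24-fold, the apolipoprotein gene APOD 5.32-fold, the immediate early gene EGR1 4.89-fold, the transcription factor gene SALL4 4.86-fold, the growth factor gene TGFB2 3.77-fold and the nucleotidase gene NT5E 3.72-fold. Of 10808 genes tested, 1600 changed, 856 higher and 744 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 253 of the higher and 181 of the lower genes changed over 2-fold. Scaled by total counts only, the split was 685 higher and 977 lower, or 41.2% higher in place of 53.5%. The count was 536 with DESeq2, 994 in cells with 1 to 5% mitochondrial counts, 897 without replicate 1 of 0 h and 771 without replicate 2 of 24 h.

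Of the followed target genes at 24 h, PGR was 5.96-fold (2.55 to 13.9), CXCL12 4.30-fold, EGR3 3.98-fold, CTSD 2.05-fold (1.81 to 2.33), XBP1 1.77-fold, SIAH2 1.4999-fold, MYC 1.25-fold (1.07 to 1.46) and CCND1 1.25-fold (1.10 to 1.42) above untreated cells, and these passed the test. NRIP1 (1.35-fold, 1.09 to 1.67) and IGFBP4 (1.21-fold, 1.06 to 1.39) each missed it by edgeR (adjusted p = 0.0534), as did RARA (0.804-fold, 0.673 to 0.959) and ESR1 (0.841-fold, 0.705 to 1.00). The MYC call ended without replicate 1 or 2 of 0 h (edgeR adjusted p = 0.136 and 0.185), 1 or 2 of 24 h (0.0793 and 0.233) and 1 or 2 of 2 h (0.0569 and 0.0617), with total counts only (0.0915), without the 5% of cells with the most counts (0.0767) or the 10% with the highest mitochondrial share (0.0647), and with DESeq2 (0.252). Calls also ended for CCND1 without replicate 2 of 0 h (edgeR adjusted p = 0.0816) or 1 of 24 h (0.0786), for SIAH2 without replicate 1 of 0 h (0.0534) and for PGR without replicate 1 of 0 h (0.131) or 2 of 24 h (0.0676) and in thinned libraries (0.0619). Among cells with 1 to 5% mitochondrial counts CCND1 (edgeR adjusted p = 0.563), MYC (0.531) and SIAH2 (0.243) had no call and ESR1 was called lower (0.0335). RARA was called lower with total counts only (edgeR adjusted p = 0.0460). NRIP1 gained a call without replicate 1 of 24 h (edgeR adjusted p = 0.0449) or without replicate 1 or 2 of 8 h (0.0316 and 0.0301). It also gained one with no filter on low counts (edgeR adjusted p = 0.0426), the 2 times alone (0.0438), thinned libraries (0.0426) and without the 5% of cells with the most counts (0.0458). IGFBP4 gained a call without replicate 1 or 2 of 8 h (edgeR adjusted p = 0.0389 and 0.0377).

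Of 54 G2M genes, 52 rose at 24 h and 0 fell, also when adjusted over the list alone (camera adjusted p = 7.51e-59), and the median log2 fold change of the list was 1.34. The mitotic kinase gene AURKA was 3.97-fold higher, the proliferation marker MKI67 3.08-fold, the topoisomerase gene TOP2A 3.09-fold and CKS2 2.09-fold. Of 43 S phase genes, 21 rose and 0 fell (28 and 0 adjusted over the list alone, camera adjusted p = 2.93e-13), with RRM2 at 1.83-fold, FEN1 at 1.72-fold and CDC6 at 2.405-fold. In the early estrogen list 33 of 65 rose and 1 fell (42 and 4 adjusted over the list alone, camera adjusted p = 3.34e-23), among them TFF1, GREB1, AREG and CTSD. Of the 12 genes lowered by estrogen, 9 fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 3.12e-11), among them PNRC1 (2.09-fold), the clusterin gene CLU (1.77-fold), TP53INP1 (2.48-fold) and BMF (2.98-fold). All 13 mitochondrially encoded genes rose, over all genes and adjusted over the list alone (camera adjusted p = 2.03e-32), with MT-ND4 at 2.18-fold, MT-ATP6 at 1.95-fold and MT-CYB at 1.87-fold, while 38.9% of cells held 10% or more mitochondrial counts. These 5 lists kept their calls with an estimated correlation (adjusted p = 0.00317 to 0.0366). In cells with 1 to 5% mitochondrial counts the mitochondrial list turned lower without a call (camera adjusted p = 0.69998).

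**Figure D2:**
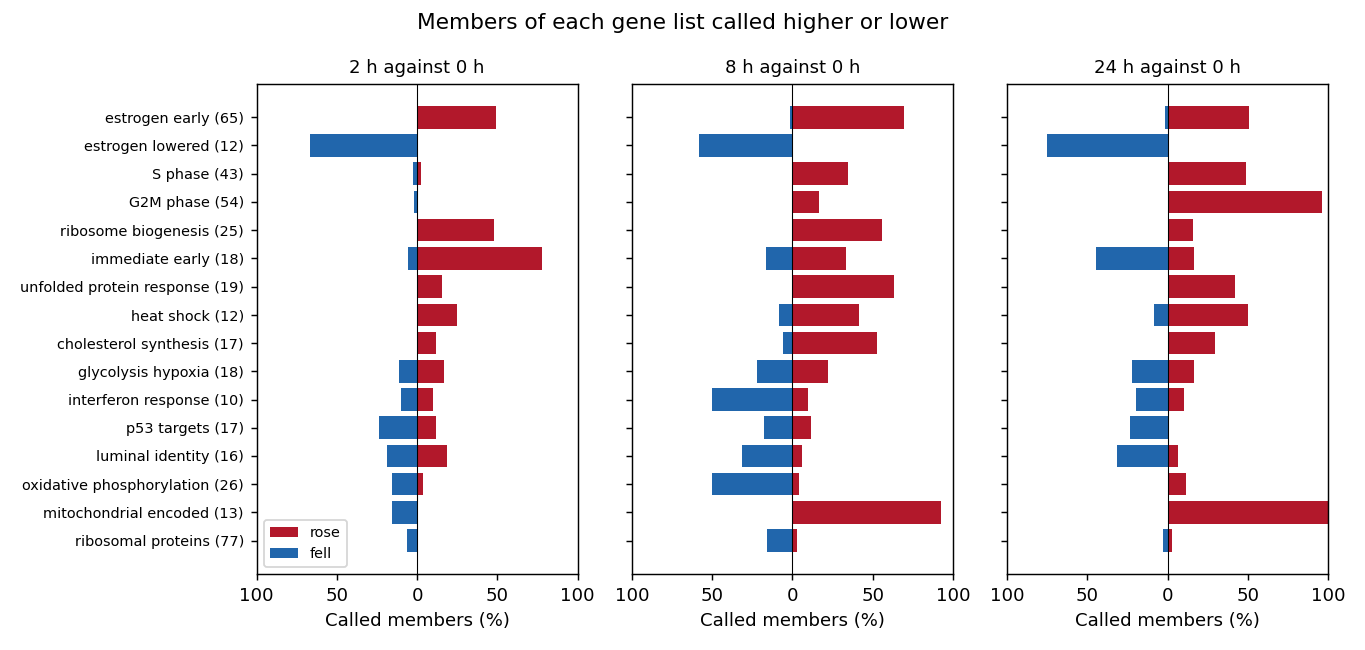
Percent of the tested members of each gene list (number in brackets) called higher (red, to the right) or lower (blue, to the left) at 2, 8 and 24 h against 0 h by edgeR's quasi-likelihood test. At 24 h, 52 of 54 G2M genes and 13 of 13 mitochondrially encoded genes were called higher.

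Other lists passed camera at 24 h with the preset correlation only. Immediate early genes fell in 8 of 18 cases and rose in 3 (8 and 4 adjusted over the list alone, camera adjusted p = 0.00663, adjusted p = 0.101 with an estimated correlation), with EGR1 and JUNB (1.91-fold) lower and EGR3 higher. Of 17 p53 targets, 4 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.000363, adjusted p = 0.167 with an estimated correlation), namely BBC3 (2.11-fold), the pro-apoptotic gene BAX (1.51-fold), PHLDA3 (1.60-fold) and BTG2 (1.68-fold). Of 25 ribosome biogenesis genes, 4 rose, also when adjusted over the list alone (camera adjusted p = 0.00888, adjusted p = 0.151 with an estimated correlation), with the nucleolin gene NCL at 1.30-fold. Of 19 genes of the unfolded protein response, 8 rose (9 adjusted over the list alone, camera adjusted p = 0.000166, adjusted p = 0.151 with an estimated correlation), among them XBP1 and HSPA5 (1.58-fold). Of 12 heat shock genes, 6 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00731, adjusted p = 0.108 with an estimated correlation), with HSPD1 at 1.65-fold and its partner HSPE1 at 1.41-fold. Of 17 cholesterol synthesis genes, 5 rose, also when adjusted over the list alone (camera adjusted p = 0.000519, adjusted p = 0.188 with an estimated correlation), among them DHCR7 (1.58-fold) and INSIG1 (1.64-fold). Of 16 luminal genes, 5 fell and 1 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.00484, adjusted p = 0.188 with an estimated correlation), with KRT18 at 0.655-fold, KRT8 at 0.748-fold and CDH1 at 1.37-fold. The luminal list lost its call without replicate 1 of 0 h (camera adjusted p = 0.0657), and the immediate early list in cells with 1 to 5% mitochondrial counts (camera adjusted p = 0.0622).

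The remaining 4 lists had no camera call at 24 h. The ribosomal protein genes showed 2 higher and 2 lower of 77 (2 and 0 adjusted over the list alone, camera adjusted p = 0.298), with RPL39L at 1.66-fold. That list was called lower without replicate 1 of 0 h (camera adjusted p = 0.000232) or replicate 1 of 24 h (0.0223), and higher in cells with 1 to 5% mitochondrial counts (6.36e-17). Of 26 nuclear oxidative phosphorylation genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.482), and the list's median of 0.02 on the log2 scale turned to −0.03 when scaled by total counts only. In cells with 1 to 5% mitochondrial counts this list was called higher (camera adjusted p = 3.90e-13). Of 18 genes of glycolysis and hypoxia, 3 rose, with LDHA at 1.94-fold, and 4 fell, with the stress gene DDIT4 at 0.702-fold (4 and 6 adjusted over the list alone, camera adjusted p = 0.771). Of 10 interferon response genes, IFI27 (2.37-fold) and IFI6 (2.19-fold) fell and ISG20 rose 1.57-fold (2 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.231). Among markers of other cells, SNAI2 was 3.28-fold lower, FN1 1.499-fold higher and HBA1, which has a near-identical neighbour gene, 3.92-fold higher, at 7.73 ± 1.55 CPM at 24 h (SD, n = 2).

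**Figure D3:**
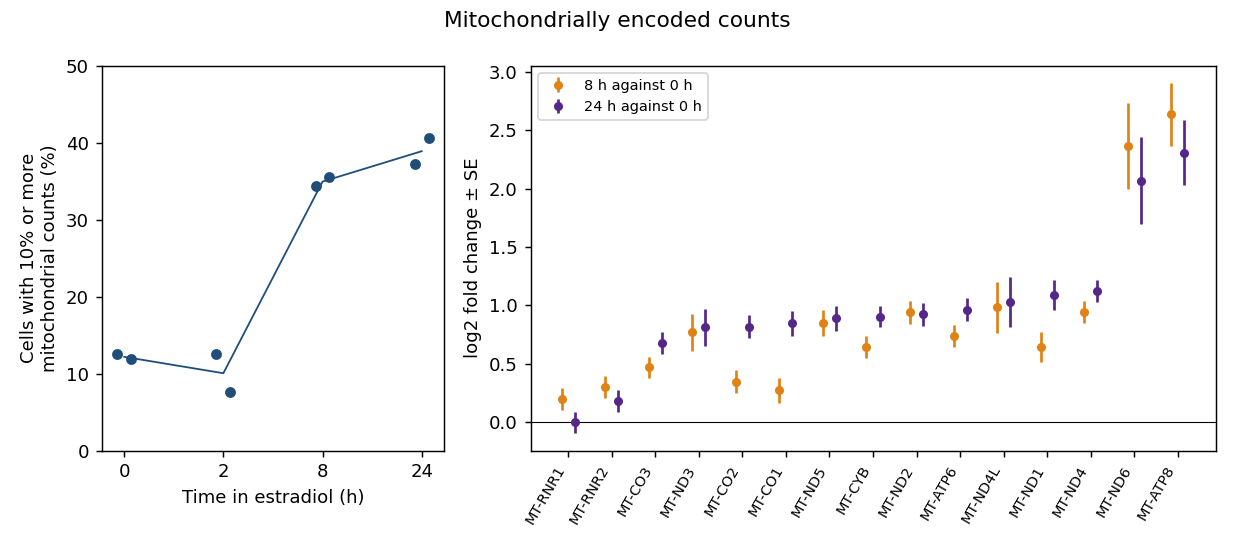
Left, percent of cells with 10% or more mitochondrial counts against time in estradiol in h, with 1 point per library and a line through the means, and right, log2 fold change with its SE at 8 and 24 h against 0 h for the 2 mitochondrial rRNA genes and the 13 coding genes. At 24 h the rRNA gene MT-RNR1 was at −0.00 ± 0.09 and the coding gene MT-ND4 at 1.12 ± 0.10.

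Direct contrasts between successive times showed what changed after the first response. From 2 to 8 h MT-ATP8 (4.79-fold), MT-ND6 (4.69-fold), C15orf48 (3.35-fold), the S phase gene WDR76 (2.97-fold) and the centromere protector gene SGO1 (2.94-fold) rose. AC011487.2 fell 8.03-fold, LIF 5.08-fold, the immediate early gene FOSL1 4.88-fold, ACHE 4.57-fold and MAB21L4 4.49-fold. Among target genes, TFF1 (1.74-fold), GREB1 (1.73-fold) and CTSD (1.44-fold) rose, and EGR3 (2.07-fold) and RARA (1.66-fold) fell. In all, 843 of 10808 genes changed, 388 higher and 455 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 199 with DESeq2, 170 in cells with 1 to 5% mitochondrial counts, 376 and 344 without replicate 1 or 2 of 2 h and 553 without replicate 2 of 8 h. WDR76 lost its call without replicate 2 of 2 h (edgeR adjusted p = 0.0589), and in cells with 1 to 5% mitochondrial counts GREB1 (edgeR adjusted p = 0.144), RARA (0.0815) and SGO1 (0.429) had none. CCND1, at 0.828-fold, missed the threshold narrowly (edgeR adjusted p = 0.0510) and passed with total counts only (0.0201). It also passed with DESeq2's size factors in edgeR (adjusted p = 0.0442), voom (0.0410), the 2 times alone (0.0475), thinned libraries (0.0346) and in cells with 1 to 5% mitochondrial counts (0.00663). NRIP1 passed without replicate 1 of 8 h (edgeR adjusted p = 0.0457) or the 5% of cells with the most counts (0.0278). MYC passed with total counts only (edgeR adjusted p = 0.0473), without the 5% of cells with the most counts (0.0343) and without the 10% with the highest mitochondrial share (0.0387).

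PIF1 was 6.61-fold higher at 24 than at 8 h, CDC25C 5.64-fold, the mitotic kinase genes AURKB 3.79-fold and NEK2 3.74-fold, and the cell cycle inhibitor gene CDKN2C 3.74-fold. The NF-kappa-B subunit gene RELB was 6.63-fold lower, NR4A1 5.61-fold, PHLDA1 5.59-fold, EGR1 4.82-fold and RASD1 3.53-fold. TFF1 rose a further 1.97-fold and GREB1 1.38-fold, while MYC was at 0.750-fold. In all, 976 of 10808 genes changed, 525 higher and 451 lower (397 and 604 when scaled by total counts only, 39.7% against 53.8% higher), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 314 with DESeq2 and 492 and 608 without replicate 1 or 2 of 24 h. Calls ended for GREB1 with DESeq2 (adjusted p = 0.0506) and without replicate 2 of 24 h (edgeR adjusted p = 0.0632), and for MYC with DESeq2 (adjusted p = 0.0914) and without replicate 1 of 24 h (0.0792) or replicate 2 of 8 h (0.0733). Among cells with 1 to 5% mitochondrial counts NEK2 (edgeR adjusted p = 0.113) and RASD1 (0.579) had no call, and with total counts only AREG (0.0333) and CCND1 (0.0114) were called lower.

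Over the whole time course 3228 of 10808 genes varied by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The highest mean was at 0 h for 918 of these genes, at 2 h for 735, at 8 h for 761 and at 24 h for 814. The count was 1097 with DESeq2's likelihood ratio test and 1707 in cells with 1 to 5% mitochondrial counts.

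The per-cell share of the early estrogen list rose from each time to the next. Without TFF1 it rose from 2 to 8 h by less than the SD between libraries and was lower at 24 h. The list's 68 genes in the table took 0.837 ± 0.00759% of a cell's counts at 0 h, 1.37 ± 0.0131% at 2 h, 1.60 ± 0.0188% at 8 h and 1.95 ± 0.139% at 24 h (SD, n = 2 libraries). In an exact permutation test over 2520 assignments of the 8 libraries to the 4 times, one-sided in the F ratio, p was 0.00952, the smallest that these permutations can give, and 0.0238 after adjustment over 5 measures. Without TFF1 the share was 0.632 ± 0.0159%, 1.06 ± 0.0125%, 1.07 ± 0.0221% and 0.961 ± 0.0163% at 0, 2, 8 and 24 h (SD, n = 2, exact permutation p = 0.0286). The change from 0 to 24 h without TFF1 was 0.329 points in place of 1.12. Without TFF1, XBP1 and CTSD it was 0.483 ± 0.0122%, 0.815 ± 2.05e-05%, 0.795 ± 0.00413% and 0.710 ± 0.00712% (SD, n = 2, exact permutation p = 0.00952). The share of the G2M list was 0.334 ± 0.0161%, 0.340 ± 0.00355%, 0.381 ± 0.00715% and 0.602 ± 0.0123% at 0, 2, 8 and 24 h (SD, n = 2, exact permutation p = 0.0286, adjusted 0.0357). The share of the S list was 0.162 ± 0.00233%, 0.169 ± 0.00603%, 0.230 ± 0.0157% and 0.240 ± 0.0213% (SD, n = 2, exact permutation p = 0.0381, adjusted 0.0381). The S list call ended without replicate 1 of 8 h or replicate 2 of 24 h (exact permutation p = 0.0667 for each) and in cells with 1 to 5% mitochondrial counts (exact permutation p = 0.181).

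The spread of the estrogen response between cells was measured after thinning each cell to 3000 counts. The Fano factor, the variance over the mean, of the early estrogen list rose from 2.92 ± 0.445 at 0 h to 3.59 ± 0.0105, 4.95 ± 0.0194 and 8.32 ± 0.544 at 2, 8 and 24 h (SD, n = 2, exact permutation p = 0.00952, adjusted 0.0238). In every library, 101 to 162 of 1000 random lists had a Fano factor at least as high. These random lists were matched on mean expression over all cells, not within a library, so at a given time their levels may differ from the list's. The correlation across cells between alternate genes of the list was 0.255 ± 0.0516, 0.264 ± 0.0402, 0.154 ± 0.0196 and −0.00117 ± 0.0742 at 0, 2, 8 and 24 h (SD, n = 2, exact permutation p = 0.0190, adjusted 0.0317). At 0 and 2 h 4 to 29 of 1000 random lists reached the observed correlation, and at 8 and 24 h 264 to 736 did. The thinned level of TFF1 went from 6.06 ± 0.454 counts per cell at 0 h to 29.6 ± 3.01 at 24 h (SD, n = 2), and TFF1 took 23.8% of the list's counts at 0 h and 50.04% at 24 h. The permutation p-values below test all 4 times together, not the difference from 0 to 24 h printed beside them. Without TFF1 the difference in the Fano factor from 0 to 24 h was 1.09 (exact permutation p = 0.505) and that in the correlation 0.0759 (exact permutation p = 0.848). For that correlation alternate genes were taken anew, so genes after TFF1 in the alphabet, XBP1 among them, changed parts. The Fano factor call also ended without TFF1, XBP1 and CTSD (0.825, exact permutation p = 0.571). Extra-Poisson variation, the Fano factor less 1 divided by the mean, is on another scale. It was 0.0886 and 0.0652 in the libraries of 0 h and 0.114 and 0.139 in those of 24 h. It had no call (difference 0.0495, exact permutation p = 0.0667). The correlation also lost its call without replicate 1 or 2 of 8 h (exact permutation p = 0.0667 and 0.0571). No call was made either between the first and second part of the list in alphabetical order (−0.0689, exact permutation p = 0.286) and in cells with 1 to 5% mitochondrial counts (−0.113, exact permutation p = 0.305).

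**Figure D4:**
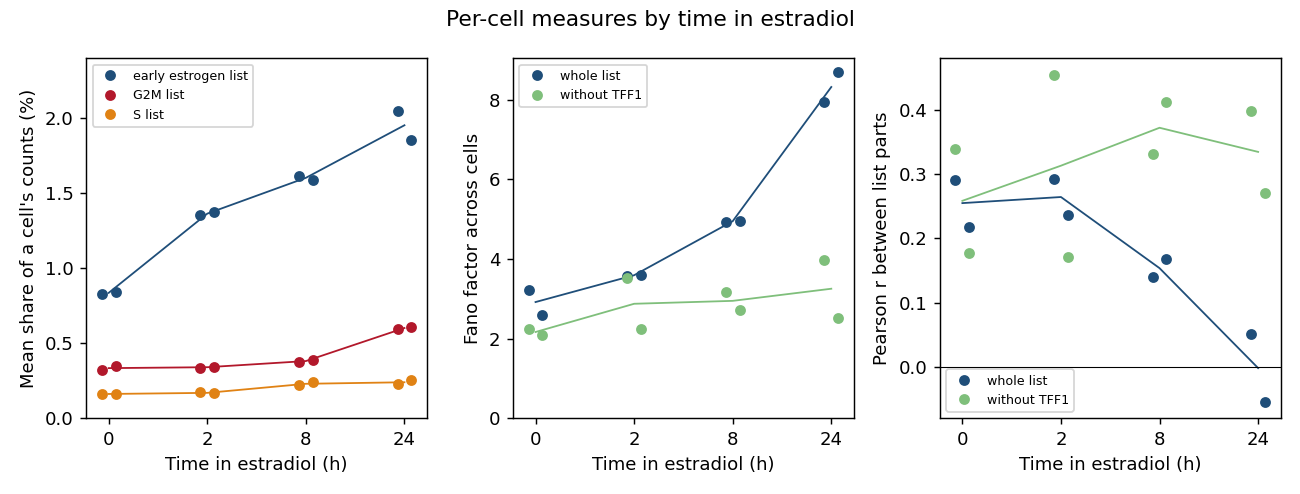
Mean percent of a cell's counts in 3 gene lists (left) and, for the early estrogen list with and without TFF1 in thinned cells, Fano factor (middle) and correlation (right), against time in estradiol in h, with libraries as points and lines through the means. The whole-list Fano factor reached 8.32 at 24 h and the whole-list correlation was −0.00117.

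The percent of cells with a count of a followed gene was compared between times. After thinning to 3000 counts, which left out 23 to 98 cells per library, GREB1 was counted in 16.1 ± 2.67% of cells at 0 h, 31.6 ± 5.79% at 2 h, 46.8 ± 1.28% at 8 h and 54.6 ± 4.17% at 24 h (SD, n = 2). AREG was counted in 14.4 ± 0.328%, 49.0 ± 0.982%, 50.3 ± 0.463% and 42.8 ± 1.72% of cells, and CCND1 in 74.1 ± 3.44%, 94.0 ± 1.59%, 85.6 ± 0.586% and 79.6 ± 1.18%. EGR3 was counted in 2.36 ± 0.414%, 19.5 ± 0.737%, 12.8 ± 0.981% and 12.3 ± 2.01%, and ESR1 in 25.3 ± 3.24%, 17.4 ± 0.169%, 23.2 ± 3.04% and 20.1 ± 1.57%. Unthinned, GREB1 was counted in 30.7 ± 0.633% of cells at 0 h and 78.0 ± 0.342% at 24 h. A Poisson draw at the mean thinned level would give GREB1 in 18.9%, 33.2%, 50.1% and 58.7% of cells at the 4 times. For EGR3 it would give 2.30%, 21.5%, 14.6% and 12.8%. For AREG it would give 15.8%, 66.8%, 62.5% and 52.8%, further above the observed percents at 2, 8 and 24 h. A rise in the percent of cells with a count can thus follow from the mean level alone. No cell type that should lack these genes was present to give the background from free RNA. None of the 16 genes passed the exact permutation test after adjustment over the 16 (smallest adjusted p = 0.0508), while 8 had an unadjusted p under 0.05. The 16 include PDZK1, which after thinning was counted in only 2 cells, both in replicate 2 of 24 h. Its test could not pass and still enlarged the family. GREB1, CCND1 and AREG each had an exact permutation p of 0.00952, the smallest these permutations can give. The adjustment over 16 could not call them unless more genes reached that value, so the lack of a call says little about them. When the 5 per-cell measures were added to the same family, a reading tried after that result was seen, GREB1, CCND1 and AREG passed (exact permutation, adjusted p = 0.0400 for each). In that family the S list share (exact permutation, adjusted p = 0.0667), the G2M list share (0.0545) and the correlation of list parts (0.0545) no longer passed.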

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

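The tests of lost RNA, of untreated libraries at later times and of a mix of cells were chosen only after the result was seen, and so were the results in cells with 1 to 5% mitochondrial counts.

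The responses of many named genes at successive times differed in a direct test by edgeR. Genes named for the largest changes from 0 h share libraries with these contrasts, a choice that favours a swing back at the next time. From 2 to 8 h the log2 change was −3.01 for AC011487.2, −2.19 for ACHE, −2.05 for MUC3A, −1.35 for PSCA and −0.73 for RARA. LIF (−2.345), PHLDA1 (−2.01), EGR1 (−1.72), LONRF2 (−1.38), NR4A1 (−1.38), FHL2 (−1.19), PMAIP1 (−1.12), EGR3 (−1.05) and FOXC1 (−1.04) were lower at 8 than at 2 h. MT-ATP8 (2.26), MT-ND6 (2.23), NECTIN4 (1.44), RAB31 (1.25), EPHA4 (1.095), ARID4A (1.09), CCNG2 (0.98), HOXC13 (0.87), TFF1 (0.80), GREB1 (0.79) and CTSD (0.53) were higher.

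From 8 to 24 h the log2 change was 2.73 for PIF1, 2.495 for CDC25C, 1.56 for TNFAIP8L1, 1.55 for KIF14, 1.46 for CKAP2L, 1.30 for ING4, 1.27 for ARHGAP36, 0.98 for TFF1, 0.66 for CCNG2 and 0.47 for GREB1. It was −2.49 for NR4A1, −2.48 for PHLDA1, −2.27 for EGR1, −1.53 for APOD, −1.48 for SLC39A14, −1.37 for CYP1B1, −1.30 for PTGES, −1.24 for SALL4, −0.94 for TGFB2, −0.93 for SLC7A5, −0.66 for RAB31 and −0.42 for MYC. CCNG2, lower at 2 h, thus rose at each later step, and RAB31 rose and then fell.

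Mitochondrially encoded counts were higher at 8 and 24 h. Depth alone is argued against, since in cells of 3000 to 6000 counts the mean mitochondrial percent at 24 h still exceeded that at 0 h by 2.454 points (6.40 ± 0.538% against 3.94 ± 0.115%, SD, n = 2). Loss of other RNA from damaged cells would raise all mitochondrial genes by 1 factor, and 2 of the 13 coding genes at 24 h and 5 of 13 at 8 h lay over 3 SEs from their median, but without MT-ATP8 and MT-ND6, whose change is uncertain in size, 0 and 2 of 11 did, so these counts exclude nothing. The 2 rRNA genes did not share 1 factor with the coding genes. The nearer of them lay 0.738 below the median of the 13 at 24 h and 0.4687 at 8 h on the log2 scale, over 3 of its SEs each time. These genes and this criterion were chosen after their values were seen, so the gap describes the data and gives no verdict on such a loss. An effect of estradiol itself cannot be told apart from time in culture or handling at harvest, because 0 untreated libraries were taken at 2, 8 or 24 h.

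The correlation between parts of the early estrogen list was lower at 24 h. TFF1 stays an unsettled candidate: without TFF1 the correlation at 24 h minus that at 0 h was 0.07595 (0.334 ± 0.0909 against 0.258 ± 0.114, SD, n = 2). Leaving TFF1 out also moved the genes after it in the alphabet, XBP1 among them, to the other part. With TFF1 kept, the first and second part of the list gave a change of only −0.0689 (exact permutation p = 0.286). The test therefore cannot tell TFF1 from the choice of parts. A mix of cells with different mitochondrial shares stays open, since the 44.24% of the fall left in cells with 1 to 5% mitochondrial counts is a difference between 0.0540 ± 0.197 at 0 h and −0.0593 ± 0.192 at 24 h (SD, n = 2), a spread too wide to decide. No biological explanation beyond time in estradiol was tested.

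Fewer genes were called at 8 h in cells with 1 to 5% mitochondrial counts. Having fewer cells is argued against as the sole cause: 0 of 20 random draws of as many cells gave as few calls as the 578 in those cells, with 889 to 1157 in the draws. Of the 1896 genes called at 8 h in all cells and tested in the 1 to 5% cells, 1825 had the same sign there. The 1 to 5% cells are part of all cells, which by itself favours the same sign. At 24 h the 1 to 5% cells gave 994 calls against 522 to 918 in the draws. What sets the difference apart from the number of cells was not tested.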

How the results depend on the processing

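Results in cells with 1 to 5% mitochondrial counts, the extra-Poisson variation and the joint family of tests were chosen only after the data were seen. The cause of a difference was not tested, except for the number of cells. DESeq2 called 270, 735, 536, 199, 314 and 1097 genes for 2, 8 and 24 h against 0 h, 8 against 2 h, 24 against 8 h and the time course, and cells with 1 to 5% mitochondrial counts gave 325, 578, 994, 170 and 1707 calls (694 for 24 against 8 h, within 1.5 times). Of 20 random draws of as many cells, 0 gave as few calls as these cells for 2 and 8 h against 0 h and 8 against 2 h, and all gave fewer for 24 h against 0 h (522 to 918) and 24 against 8 h (295 to 604). Only for the time course did these cells lie within the draws (1398 to 1833). In those cells NRIP1 at 8 h turned to −0.20 on the log2 scale, the mitochondrial list turned lower at 8 h (camera adjusted p = 1.63e-22) and 24 h (0.69998), which the choice of cells by mitochondrial share can set by itself, and the ribosomal protein list turned higher at 8 h (0.186) and 24 h (6.36e-17). An estimated correlation left 12 of 32 list calls. Leaving out 1 library gave 451 to 1110, 1211 to 2040, 771 to 1856, 344 to 854 and 492 to 978 calls in the 5 pairwise comparisons, in that order. Changes from 0 to 24 h ranged from 0.0632 to 0.0933 points for the S list and from −0.309 to −0.204 for the correlation of list parts. Calls of the per-cell measures test all 4 times together, not these changes. Extra-Poisson variation, which is on a scale other than that of the Fano factor, changed by 0.0495 without a call. The Fano factor changed by 1.09 without TFF1 and 0.825 without TFF1, XBP1 and CTSD, both without a call. It changed by 3.18 in cells thinned to 1500 counts and by 3.55 in the 1 to 5% cells, in place of 5.399, and kept its call in both. The correlation changed by 0.0759 without TFF1, −0.0689 with alphabetical parts and −0.113 in the 1 to 5% cells, and the S share there by 0.0546 points, all without a call. In cells thinned to 1500 counts the correlation changed by −0.100 in place of −0.256 and kept its call (exact permutation p = 0.0476). The joint family called 3 of the followed genes, against 0, and ended the calls of the S share (adjusted p = 0.0667), the G2M share (0.0545) and the correlation (0.0545). Without TFF1 the early estrogen share changed by 0.329 points in place of 1.12 and kept its call. Differences between replicates 1 and 2 correlated at −0.0529 to 0.0969 between times, which does not settle whether replicate numbers pair the libraries. With the replicate block, 959, 2088, 1607, 874, 1008 and 3273 genes were called, the immediate early list at 8 h gained a call, and the 5 per-cell measures kept their values (1.12, 0.0782, 0.268, 5.399 and −0.256) but had no call, in a permutation whose smallest p is 0.0417. Requiring 1000 counts left out 0 cells and so tested nothing. Of the named-gene results under all alternatives, 2805 kept their side of the threshold, 60 lost and 27 gained a call and 1 reversed, and of list results 482, 29, 13 and 4. A change of sign was counted as reversed only where the main result or the alternative had a call, so results without a call may have changed sign. The 2805 include the repeat that required 1000 counts. With 2 libraries per time, 1.5-fold changes were mostly missed on simulated counts. Far fewer genes were changed there than were called in the data, so the share missed in the data may differ.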

Other observations

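The test of the mitochondrial rRNA genes was chosen only after the result was seen, and those genes after their values were seen.

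MT-RNR1 and MT-RNR2, the rRNA genes of the mitochondrial genome, parted from its coding genes. At 24 h MT-RNR1 was at −0.00 ± 0.09 (SE) and MT-RNR2 at 0.18 ± 0.09 on the log2 scale, neither called by edgeR (adjusted p = 0.993 and 0.192), while the median of the 13 coding genes was 0.92. At 8 h MT-RNR1 was at 0.20 ± 0.09 and MT-RNR2 at 0.30 ± 0.09, and MT-RNR2 was called (edgeR adjusted p = 0.0165), beside a median of 0.77. In each of the 8 libraries, cells with 10% or more mitochondrial counts had a higher median count than cells with 1 to 5%, by 1.16 to 1.88 times.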
